A study of Danio rerio with 11 samples.

How the data were processed

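Livers of 4-day zebrafish larvae were profiled on 1-colour Affymetrix zebrafish arrays, 1 array per sample, as 4 vehicle-injected wild-type controls, 4 azacytidine-injected wild-type samples and 3 vehicle-injected ahcy -/- mutants. Per the labels, RNA was amplified in 2 rounds before labelling; they name both biotin and Cy3 as the label, and the arrays were read as 1-colour. Groups and sample numbers come from the sample titles and characteristics. The labels do not say whether samples came from separate clutches or pools of larvae, so p-values measure only the spread between these samples, which may be technical.

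The deposited values are log2 expression levels, 1 per probe set and array, made with GCRMA and Partek per the submitters' processing notes, which give no version. GCRMA subtracts a sequence-dependent background, normalises across arrays and summarises probes, so low levels carry background uncertainty and levels near the top of the scale are compressed; any filter the authors applied is not given in the sources used here. The table held 12830 probe sets; 46 array control probe sets were left out, so 12784 were tested, with no further filter or normalisation. The table held 0 columns of other samples.

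Probe sets were named from the platform annotation: 8994 had 1 gene symbol, 110 several and 3680 none, and no gene was named from the last 2 kinds. Symbols were updated through the gene ID for 8926 probe sets, which changed 1. The 7795 genes include 981 with several probe sets; the probe set with the highest mean over all arrays stood for its gene, and probe sets of a gene can disagree. No detection calls were used; where all arrays of a group lay below their own 10th percentile, a named gene's difference is also given with those levels set at that percentile, a bound added after seeing the data. Hepatocyte markers count as away from both ends of the scale when all control levels lay above that percentile and over 2 below the highest level of their array. A further 719 tested probe sets carry names that mark possible sharing of probes between transcripts.

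Each probe set was fitted with limma 3.58.1 in R 4.3.3, all 11 arrays in 1 linear model of 3 group means (8 residual degrees of freedom), with empirical Bayes moderation with a mean-dependent variance trend, and tested 2-sided for azacytidine minus control, mutant minus control and mutant minus azacytidine. Benjamini-Hochberg adjustment ran over all probe sets within each comparison, with calls at an adjusted p under 0.05. Through the same functions, 200 changed probe sets among 12784 were simulated in 5 rounds; for azacytidine against control 39.4% were recovered at a log2 change of 1, 90.7% at 2 and 98.2% at 3, and for mutant against control 27.5%, 87.2% and 95.5%. False calls were 5.4% and 4.8% of calls. A list shifted by 1 in the simulated azacytidine arrays was called in 5 of 5 rounds and 1 other list was called over all rounds. The simulated noise was independent between probe sets, without the correlation between list members of the real arrays. These rounds therefore do not show how often the list test calls falsely on real arrays.

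A set of 42 gene lists was fixed before the data were examined: 12 of cell types that liver or a liver dissection could hold and 30 of pathways and complexes. Symbols were matched to current names and synonyms, a synonym only when its first 2 letters agreed. Lists with at least 5 measured genes (41 of 42) were tested with camera (preset correlation 0.01, 1 probe set per gene), which ranks a list against other genes, adjusted over lists; camera with an estimated correlation and fry, which tests whether a list moves 1 way without comparing it with other genes, were run beside it. No list call held with an estimated correlation, where the lowest adjusted p was 0.18, 0.19 and 0.21 in the 3 comparisons and 7, 6 and 6 lists had an unadjusted p under 0.05; fry called 6, 20 and 25 lists. List members can be shared: 10 of 22 hepatocyte markers also stand in another list.

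Named genes followed a rule also fixed before the data were examined: ahcy and dnmt1; the 8 largest called changes in each direction against control, and 5 for mutants against azacytidine, among genes whose arrays all lay outside the other group's range; up to 5 genes per direction called in both comparisons with control and up to 5 called in opposite directions; and up to 4 called members of each list by smallest p, or up to 2 largest changes where none was called. Of the list members the rule gives, the text names some. Unnamed loci were passed over. Comparisons with shared controls were set beside 100 simulated data sets of unchanged groups and beside splits of the controls.

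Alternatives were the variance prior without trend or robust, filters on dim probe sets, cyclic loess, centring, fits of only 2 groups, array weights, the sample number as a fixed or random block, a minimum change of 1, genes averaged over probe sets, an unmoderated comparison with unequal variances, and each array left out. Leaving out controls 2 and 4 together, a covariate of muscle, epidermis and neural marker levels, and lists without shared members were added after seeing the data. That covariate differs between the groups, so it removes group differences along with tissue content.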

Results

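Gene expression was measured in livers dissected from zebrafish larvae at 4 days after fertilisation, in 3 groups. Control larvae and azacytidine-treated larvae were wild type at ahcy, and received vehicle or 1 mM azacytidine by injection into the yolk at 2 days. Azacytidine is a cytidine analogue that, once built into DNA, traps DNA methyltransferases. The ahcy mutants carried the genotype -/- at ahcy and received vehicle. The gene encodes S-adenosylhomocysteine hydrolase, the enzyme that removes the by-product of S-adenosylmethionine-dependent methylation. The series asked which genes change when methylation is inhibited by either route. The control group held 4 arrays, the azacytidine group 4 and the mutant group 3, so the number of arrays limits the precision of each value below. The deposited log2 levels had array medians of 6.04 ± 0.08 in controls (SD, n = 4), 5.93 ± 0.04 with azacytidine (SD, n = 4) and 6.15 ± 0.02 in mutants (SD, n = 3). Across probe sets, which are not independent replicates, Pearson's correlation between arrays ranged from 0.901 to 0.947 among controls, from 0.932 to 0.963 among azacytidine arrays and from 0.917 to 0.951 among mutants. It ranged from 0.814 to 0.909 between controls and mutants. Changes of single genes are given as log2 differences ± standard error from the limma fit over all 11 arrays. For differences in the mean of a whole list, the ± is an unmoderated standard error. It comes from the spread of the list means over the arrays of the groups compared.

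The ahcy transcript itself was at 12.39 ± 0.08 in controls (SD, n = 4) and 12.34 ± 0.22 with azacytidine (SD, n = 4), and at 12.11, 11.47 and 11.50 in the 3 mutants. It fell by 0.70 ± 0.16 in mutants against controls (adjusted p = 0.017), a call that was lost without mutant 4 or mutant 6 and when the variance prior had no trend. The labels do not say where the mutation lies, so the level of this probe set does not check the genotype. The maintenance DNA methyltransferase gene dnmt1 was at 6.50 ± 0.73 in controls (SD, n = 4), and its changes of 0.27 ± 0.37 with azacytidine (adjusted p = 0.81) and 0.79 ± 0.40 in mutants (adjusted p = 0.24) did not pass the test. Without control 4 the change in mutants was 1.14 and passed it.

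Marker lists for cell types other than hepatocytes differed between arrays. The mean level of 21 neural markers was 8.31 in control 4 and 7.08 in control 8 against 5.91 and 5.25 in controls 1 and 2, between 4.73 and 5.31 with azacytidine and between 6.76 and 7.42 in mutants. The mean of 17 exocrine pancreas markers was 9.73 in control 2, against 5.43 to 7.26 in the other controls and 4.98 to 6.03 in mutants. The mean of 10 eye and lens markers was 7.90 in control 4 and at most 6.30 on any other array. Skeletal muscle and epidermis markers were highest in mutants, with group means 1.21 and 1.43 above controls respectively.

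**Figure D1:**
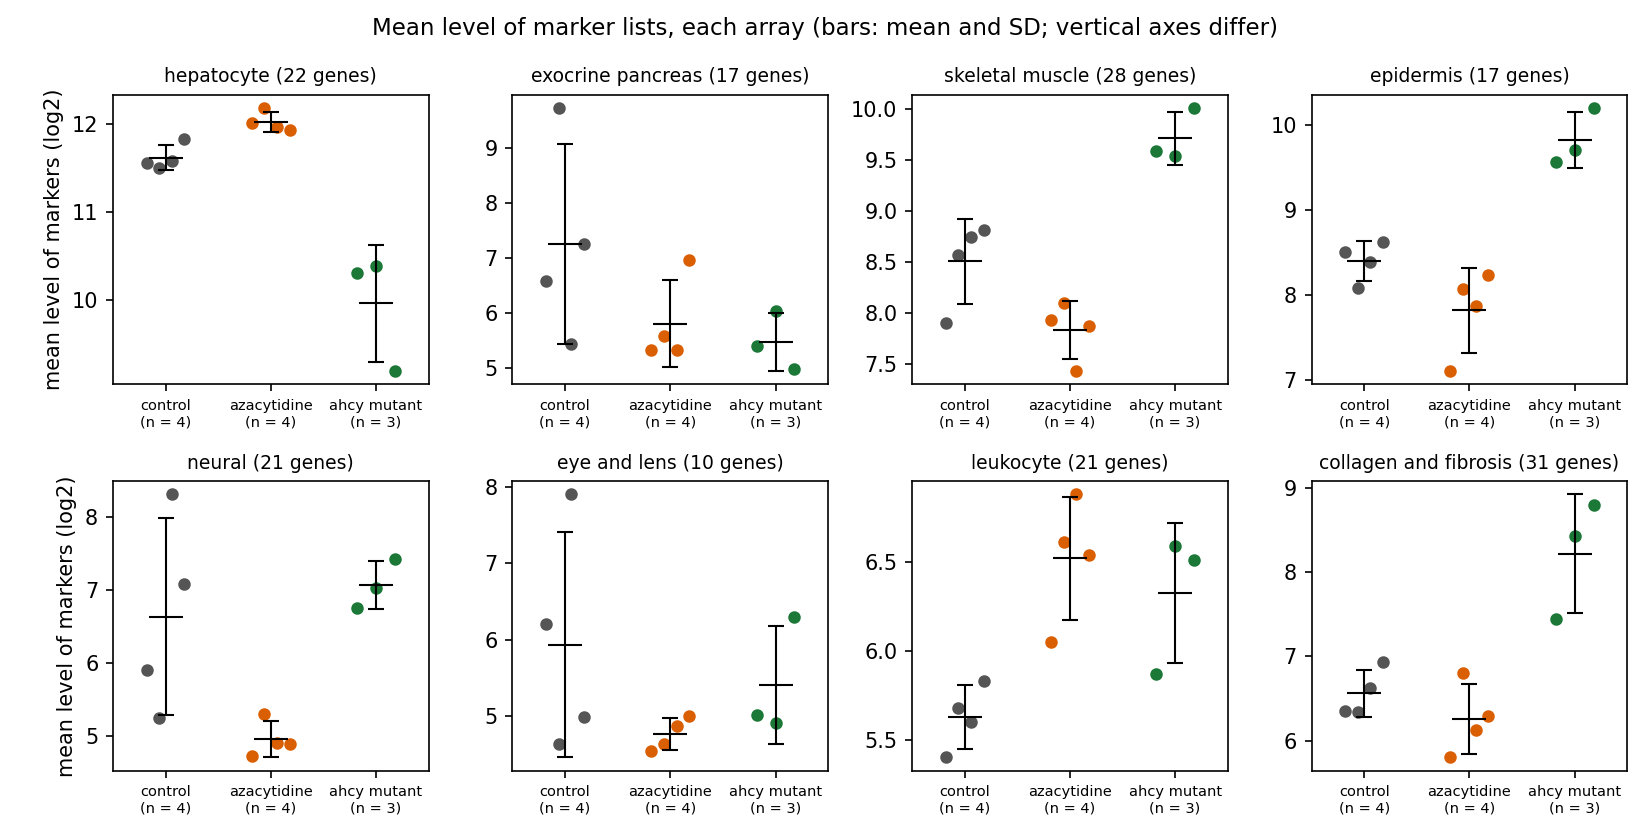
Mean log2 level of the measured members of 8 gene lists on each array; each point is 1 array, and bars give the group mean and SD (control n = 4, azacytidine n = 4, ahcy mutant n = 3). The hepatocyte mean lies between 11.50 and 11.83 in controls, between 11.93 and 12.18 with azacytidine and between 9.19 and 10.39 in mutants.

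Azacytidine against vehicle asked what the drug changed in wild-type livers. The genes named first are those with the largest called changes among named genes whose arrays did not overlap between the groups. The ubiquitin-like modifier gene isg15, a classical interferon target, rose by 5.91 ± 0.65, from 3.56 ± 0.16 in controls (SD, n = 4) to 9.47 ± 1.59 (SD, n = 4). Its control levels lay below the 10th percentile of each control array (4.22 to 4.45), and against that percentile the rise is at least 5.14. The invariant chain genes cd74a and cd74b, whose products escort MHC class II molecules, rose by 5.18 ± 0.46 and 4.18 ± 0.49, and b2m, the light chain of MHC class I, rose by 4.84 ± 0.49. The transcription factor gene irf1b rose by 4.22 ± 0.75, the terminal complement gene c7b by 4.03 ± 0.59, lemd1 by 3.79 ± 0.45 and the hepatic lipase gene lipca by 3.59 ± 0.51. Adjusted p for these 8 genes lay between 0.0011 and 0.028. Azacytidine array 1 had the lowest level of isg15, cd74a, b2m and irf1b within its group. The naming rule itself required these levels to lie above the highest control.

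In total 51 probe sets were called higher and 23 lower of 12784 tested, representing 34 and 13 named genes. At an unadjusted p under 0.05 the balance ran the other way, with 669 higher and 1270 lower. Among named genes without overlap, the largest falls were in the transcriptional repressor gene nfil3-5, which fell by 2.78 ± 0.35, and in the clock gene per2, which fell by 2.69 ± 0.46. Falls of 1.96 ± 0.33, 1.94 ± 0.33 and 1.87 ± 0.37 followed for rtn1a, znrf1 and tmem38a. The remaining 3 of the 8 named falls, in ptprna, pvalb3 and actn3b, were 1.70 ± 0.31, 1.5 ± 0.29 and 1.22 ± 0.24. Of these, pvalb3 and actn3b encode the muscle proteins parvalbumin and alpha-actinin. The mean of the skeletal muscle list differed by -0.67 ± 0.25 with azacytidine from controls, and that of the neural list by -1.68 ± 0.68. With the covariate of muscle, epidermis and neural marker levels, only nfil3-5 of the 8 named falls kept its call (limma adjusted p = 0.04). For per2 the fall was then 1.91 (limma adjusted p = 0.51). A part of these falls may thus follow tissue content, which that covariate cannot separate from the treatment.

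**Figure D2:**
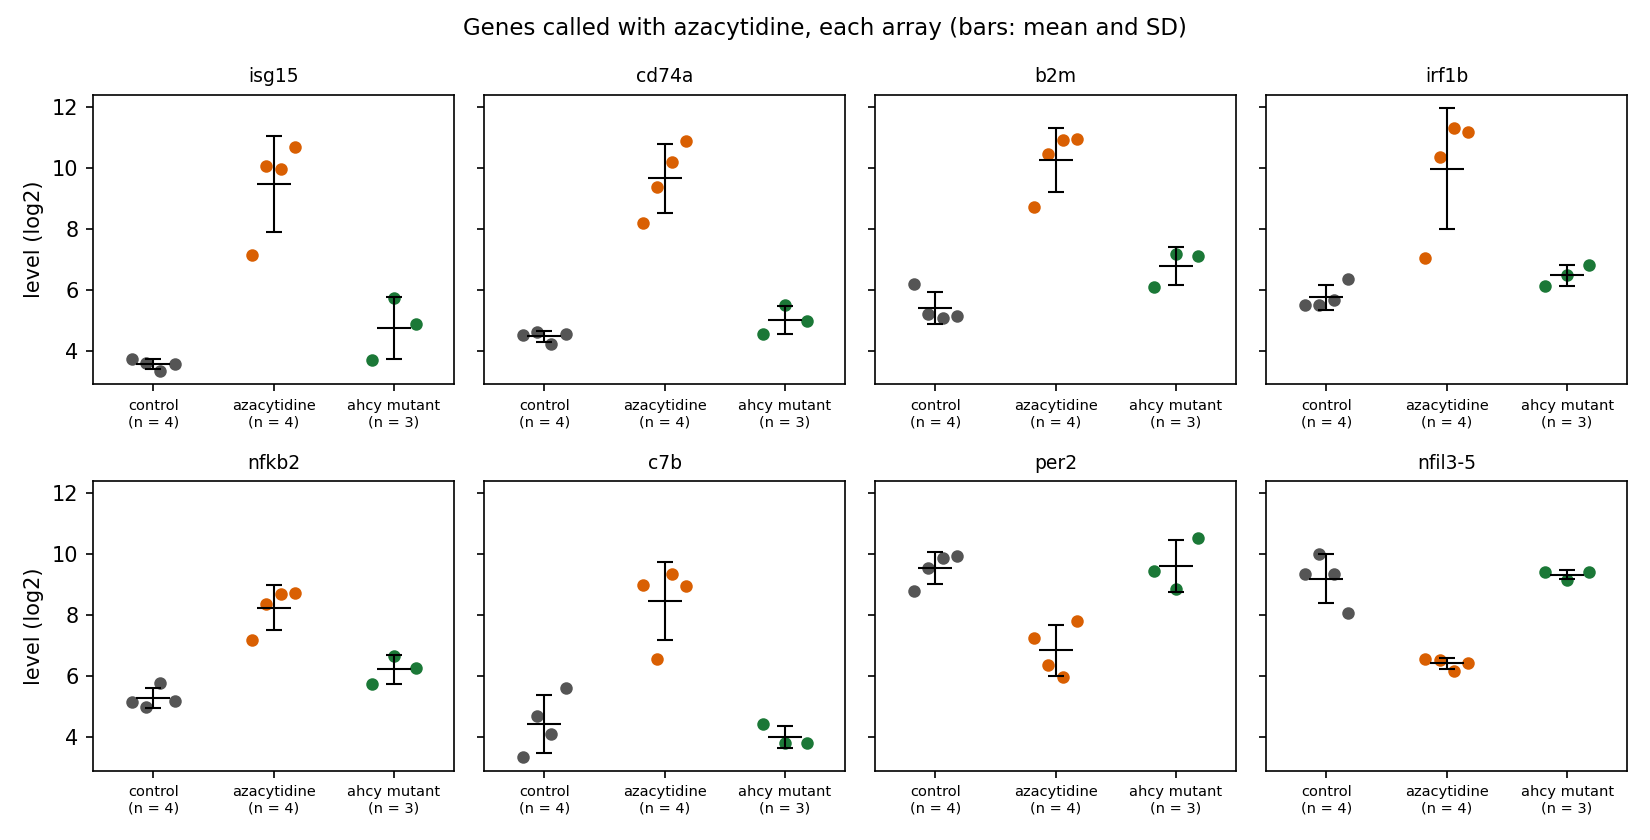
Log2 level of 8 genes called in azacytidine-treated livers on each array; points are arrays, and bars give the group mean and SD (control n = 4, azacytidine n = 4, ahcy mutant n = 3). For isg15 the azacytidine mean is 9.47 against 3.56 in controls, and for nfil3-5 it is 6.42 against 9.20.

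By gene list, 6 of 13 measured antigen presentation genes rose with azacytidine, or 9 when adjusted over the list alone, and none fell. Besides cd74a, cd74b and b2m these included the tapasin gene tapbp.1 (2.87 ± 0.47), and the median change was 2.05. The list ranked above other genes (camera adjusted p = 5e-15 with the preset correlation; adjusted p = 0.18 with an estimated correlation). Of 12 interferon response genes 3 rose (4 when adjusted over the list alone): isg15, irf1b and the guanylate-binding protein gene gbp1 (2.85 ± 0.56). All 12 estimates were positive (adjusted p = 6.9e-07; adjusted p = 0.22 with an estimated correlation). Of 18 inflammation genes 2 rose (7 when adjusted over the list alone), both of the NF-kB system: nfkb2 by 2.98 ± 0.36 and the inhibitor gene nfkbiab by 1.93 ± 0.35. That list ranked higher too (adjusted p = 5.2e-07; adjusted p = 0.18 with an estimated correlation). Of 15 complement genes, c7b and c4b (1.80 ± 0.34) rose, and adjusted over the list alone 4 were higher and 1 lower (list adjusted p = 2e-04; adjusted p = 0.22 with an estimated correlation). Of 21 leukocyte markers 2 rose, cd74a and cd74b, which the antigen presentation list also holds, and 7 were higher when adjusted over the list alone. The leukocyte list ranked higher (adjusted p = 2.7e-06; adjusted p = 0.26 with an estimated correlation). Single members or pairs rose in further lists. Of 17 lipoprotein genes these were lipca and the apolipoprotein gene apoc4 (1.76 ± 0.31), and of 33 oxidative stress genes the thioredoxin gene txnb (2.2 ± 0.33) and keap1a (1.21 ± 0.23). Of 33 p53 and damage genes rps27l rose (1.39 ± 0.16), and of 22 hepatocyte markers ahsg1 rose (1.87 ± 0.31). Adjusted over the list alone, 2 lipoprotein, 2 oxidative stress and 3 hepatocyte genes were higher, and 3 p53 genes were higher and 2 lower. The lipoprotein, oxidative stress and hepatocyte lists ranked higher at adjusted p = 0.005, 0.023 and 2.9e-05 (adjusted p = 0.5, 0.44 and 0.5 with an estimated correlation). The p53 list did not pass (adjusted p = 0.14).

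Several lists ranked higher or lower with azacytidine although at most 1 member passed the test over all probe sets. Among 38 ER stress genes, 35 estimates were positive with a median of 0.57. None was called, 20 had an unadjusted p under 0.05 in the limma fit, and 14 were called higher when adjusted over the list alone (camera adjusted p = 1.5e-13; adjusted p = 0.18 with an estimated correlation). The changes of pdia4 and herpud1 were 1.95 ± 0.46 and 1.71 ± 0.39 (adjusted p = 0.084 and 0.072). Among 12 cholesterol synthesis genes 6 were called higher when adjusted over the list alone (list adjusted p = 2.8e-05; adjusted p = 0.2 with an estimated correlation). The largest change there was that of msmo1 at 1.99 ± 0.50 (adjusted p = 0.095), which was 2.5 and passed the test without azacytidine array 1. The 38 proteasome, 61 cell cycle and 15 coagulation genes had medians of 0.38, 0.40 and 0.32, with 1, 0 and 3 members called when adjusted over the list alone. In limma 9, 12 and 4 of them had an unadjusted p under 0.05, 1 of the cell cycle genes being lower. Those lists ranked higher (adjusted p = 2.2e-09, 6.1e-09 and 1e-04; adjusted p = 0.18, 0.37 and 0.41 with an estimated correlation). On the lower side, the neural list had a median of -1.89, with 17 of 21 members called lower when adjusted over the list alone (adjusted p = 2e-10; adjusted p = 0.31 with an estimated correlation). Its members sncb and syt1a differed by -3.20 ± 0.89 and -2.78 ± 0.79 (adjusted p = 0.12 and 0.13), and over the fits without 1 array they ranged from -4.14 to -2.44 and from -3.64 to -2.0. Both were weakest without control 4 and passed the test only without control 2. The skeletal muscle list, of whose 28 members only pvalb3 fell, had a median of -0.61, and 7 members were lower when adjusted over the list alone. The epidermis, exocrine pancreas, endocrine pancreas and eye and lens lists had medians of -0.75, -1.83, -0.83 and -1.18, with 5, 0, 0 and 0 members called lower when adjusted over the list alone. In limma 5, 6, 2 and 3 of their members had an unadjusted p under 0.05, all lower. These 5 lists ranked lower (adjusted p = 2.6e-08, 0.0015, 2e-04, 0.0088 and 0.0088; adjusted p = 0.37, 0.5, 0.59, 0.42 and 0.59 with an estimated correlation). Some control arrays had list means within the azacytidine range. For eye and lens these were controls 2 and 8 (4.64 and 4.99, range 4.55 to 5). For exocrine pancreas they were controls 1 and 4 (6.58 and 5.43, range 5.33 to 6.97). Control 2 was the one for endocrine pancreas (4.89, range 4.58 to 5.21) and epidermis (8.08, range 7.1 to 8.23). The 72 ribosomal protein genes, of which rps27l rose, ranked lower with a median of -0.06 that became 0.04 when arrays were centred (adjusted p = 0.025; adjusted p = 0.85 with an estimated correlation).

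No member was called in the lists of DNA methylation and chromatin silencing (30 genes), germline and oocyte genes (17) or the methionine cycle (27). Their medians were -0.06, -0.11 and 0.16, the first of which was 0.03 or 0.04 under the other scalings, and none of these lists ranked apart (adjusted p = 0.95, 0.99 and 0.4). In limma, unadjusted p was under 0.05 for 7, 1 and 4 of their members. Adjusted over the list alone, 2 DNA methylation genes were higher and 1 lower, 1 germline gene was higher, and 0 methionine cycle genes were called. The largest changes among them included gadd45ga at 1.59 ± 0.45 (adjusted p = 0.12) and tdrd5 at 2.04 ± 0.47 (adjusted p = 0.073), which was 1.43 and passed the test without control 4. The cell type lists of biliary, intestinal, erythrocyte and endothelial markers had no called member and did not rank apart. The same held for fat synthesis, fatty acid oxidation, bile acids, heat shock, xenobiotic metabolism, respiratory chain, sugar metabolism, amino acid catabolism, collagen, hedgehog, Notch, liver transcription factors and cilia genes. Over these 20 lists unadjusted p in limma was under 0.05 for 20 members that were higher and 25 that were lower, and adjusted over each list alone 5 were higher and 5 lower. The 2 measured PDGF genes were too few to test.

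Single arrays decided much of the azacytidine count, and centring arrays on their medians gave 97 higher and 27 lower, a covariate of muscle, epidermis and neural marker levels 10 and 4. Without control 4 there were 28 higher and 4 lower, without control 8 40 and 8, without control 2 59 and 94, without azacytidine array 1 77 and 17, and without mutant 4 46 and 15. Without azacytidine arrays 2, 5 and 6 in turn there were 31 and 9, 35 and 6, and 31 and 12. The calls of isg15, cd74a, b2m, cd74b, c7b, lemd1, lipca, nfkb2, txnb, rps27l and nfil3-5 held in each fit that left out 1 array. By contrast, irf1b lost its call in 6 of the 11 such fits (3.78 to 5.20), tmem38a in 10, keap1a in 9, gbp1 and actn3b in 8, and c4b, ptprna and pvalb3 in 7. The calls of nfkbiab were lost in 5, those of per2, rtn1a, znrf1, tapbp.1 and apoc4 in 4, and that of ahsg1 in 3.

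The ahcy mutants against controls asked what loss of the enzyme changed. The genes named first were chosen in the same way. The acute phase gene crp fell by 6.08 ± 0.23, a 67.8-fold difference, from 12.14 ± 0.35 in controls (SD, n = 4) to 6.05 ± 0.35 in mutants (SD, n = 3), and the related crp3 by 4.82 ± 0.38. The cytochrome gene cyp4v2a fell by 5.46 ± 0.55. Its mutant levels (0.46 to 2.65) lay below the 10th percentile of those arrays (4.37 to 4.51), and set at that percentile they give a difference of -2.58. The gene tdo2a, which encodes the tryptophan-degrading dioxygenase, fell by 5.12 ± 0.43, the protease inhibitor gene a2m2f by 4.91 ± 0.35, igfbp1b by 4.71 ± 0.48, dhrs11b.2 by 4.59 ± 0.24 and the malic enzyme gene me1 by 4.55 ± 0.37. The largest rises without overlap were in gbp1 (3.84 ± 0.61), cfl1l (3.74 ± 0.76), the chemokine gene cxl34b.11 (3.73 ± 0.62), the muscle regulator gene myog (3.56 ± 0.38), apodb (3.18 ± 0.70), the collagen gene col10a1a (3.10 ± 0.51), ch25hl1.1 (3.09 ± 0.43) and the inflammasome adaptor gene pycard (3.09 ± 0.54). Mutant 3 had lower levels of cfl1l (7.66 against 10.93 and 12), apodb (6.09 against 8.77 and 9.68) and pycard (7.29 against 9.53 and 10.14) than mutants 4 and 6. Over the fits without 1 array the changes ranged from 2.84 to 5.01 for cfl1l, 2.43 to 4.22 for apodb, 2.99 to 4.46 for cxl34b.11 and 2.51 to 3.93 for pycard. Each was lowest without mutant 6 and highest without mutant 3. In total 797 probe sets were called higher and 750 lower, representing 507 and 559 named genes, and 1947 and 1446 had an unadjusted p under 0.05.

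Among 22 hepatocyte markers, 17 fell and none rose (18 lower when adjusted over the list alone), with a median of -1.44. They included ahsg1 (-4.24 ± 0.33), apom (-2.19 ± 0.29) and serpina1l (-0.84 ± 0.09), and the list ranked lower (camera adjusted p = 4.7e-14; adjusted p = 0.19 with an estimated correlation). On the same arrays the means of skeletal muscle and epidermis markers were 1.21 ± 0.26 and 1.43 ± 0.22 above controls and that of biliary markers 0.46 ± 0.04 above. The difference between the 3' and 5' array control probe sets for muscle actin was 5.59 to 6.21 on the mutant arrays and 3.16 to 4.92 on the control arrays, while that between the 3' and middle ones was 1.8 to 2.89 and 2.76 to 3.92. Of 26 fatty acid oxidation genes 13 fell, or 23 when adjusted over the list alone. Among them were the peroxisomal genes hsd17b4 (-2.26 ± 0.25, its other probe set -0.18) and ehhadh (-2.23 ± 0.31) and the carnitine palmitoyltransferase gene cpt2 (-1.95 ± 0.29; list adjusted p = 2e-11; adjusted p = 0.19 with an estimated correlation). Of 76 respiratory chain genes 25 fell, or 39 when adjusted over the list alone, such as ndufb9 (-1.53 ± 0.23) and ndufa2 (-0.74 ± 0.12; list adjusted p = 1.3e-12; adjusted p = 0.19 with an estimated correlation). Of 36 amino acid catabolism genes 16 fell (18 lower and 1 higher when adjusted over the list alone), led by tdo2a, kmo (-2.75 ± 0.35) and hgd (-2.30 ± 0.25; list adjusted p = 4e-08; adjusted p = 0.19 with an estimated correlation). Of 27 methionine and one-carbon genes 5 fell, or 9 when adjusted over the list alone. They included gnmt (-2.5 ± 0.26) and gamt (-1.91 ± 0.28), both methyltransferase genes that use S-adenosylmethionine, and the methionine synthase gene mtr (-1.39 ± 0.25; list adjusted p = 0.00057; adjusted p = 0.19 with an estimated correlation).

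**Figure D3:**
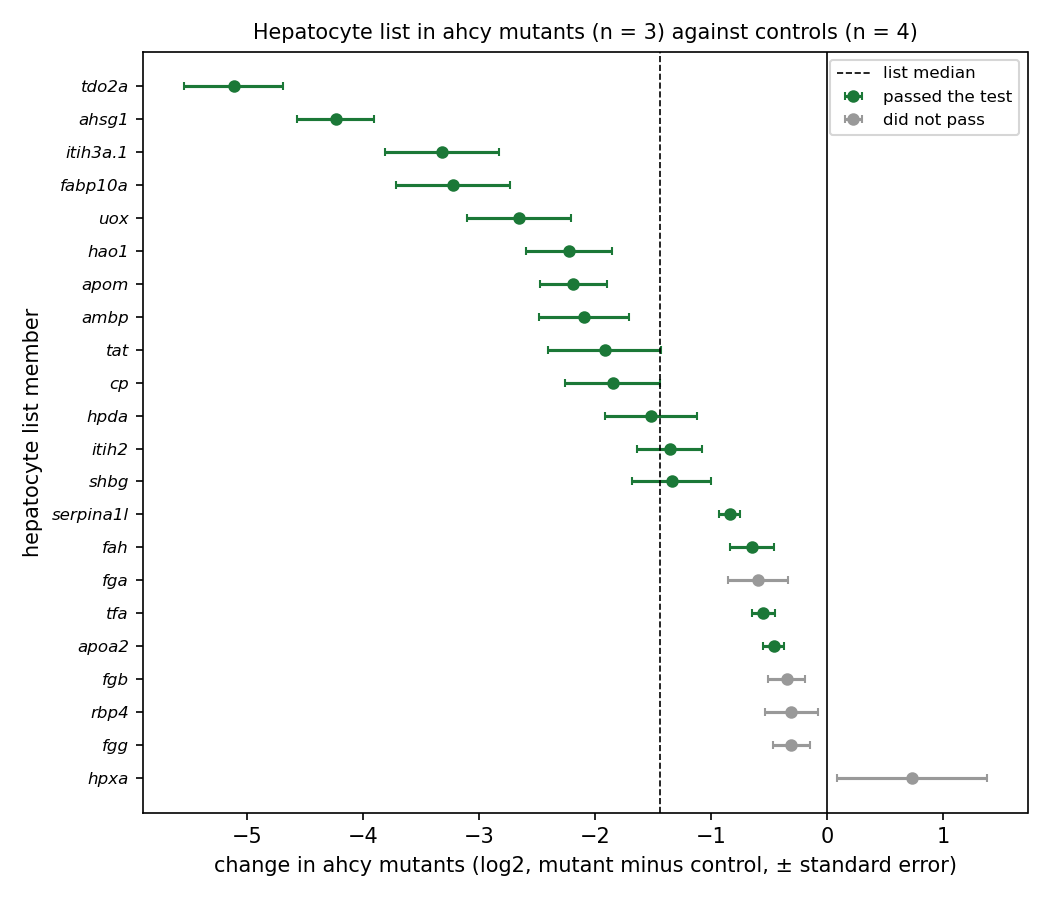
Log2 change of each of the 22 measured hepatocyte list members in ahcy mutants (n = 3) against controls (n = 4); points are limma estimates, bars their standard errors, and the dashed line the list median of -1.44. The 17 called members, all lower, run from -5.12 for tdo2a to -0.46 for apoa2.

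Plasma protein lists moved the same way. Of 15 complement genes 7 fell, among them masp2 (-3.95 ± 0.36) and c4b (-3.06 ± 0.37). Of 15 coagulation genes 5 fell, among them f7i (-4.03 ± 0.33) and f7 (-2.80 ± 0.37), and of 17 lipoprotein genes 5, among them apoba (-3.0 ± 0.40). In these 3 lists 8, 7 and 7 were lower and 2, 0 and 1 higher when adjusted over the list alone. Their camera adjusted p values were 0.001, 1.3e-05 and 8.2e-05, with adjusted p = 0.19, 0.21 and 0.21 with an estimated correlation. Of 38 ER stress genes 13 fell, or 19 when adjusted over the list alone (list adjusted p = 1.1e-07; adjusted p = 0.19 with an estimated correlation). They included the chaperone genes hspa5 (-1.70 ± 0.24) and dnajc3a (-2.81 ± 0.35), and manf (-2.13 ± 0.33, its other probe set -0.55). Of 25 xenobiotic genes 9 fell (12 when adjusted over the list alone), including cyp1a (-2.61 ± 0.44). Of 12 bile acid genes 5 fell, including hsd3b7 (-2.90 ± 0.32) and slc27a2a (-3.69 ± 0.50), while 1 rose, and adjusted over the list alone 6 were lower and 2 higher. These 2 lists ranked lower (adjusted p = 2.5e-05 and 0.016; adjusted p = 0.19 and 0.25 with an estimated correlation). Of 17 exocrine pancreas markers only prss1 fell (-3.47 ± 1.01), a call lost in 8 of the 11 fits without 1 array, and 0 were called when adjusted over the list alone, with 7 at an unadjusted p under 0.05 in limma. The list median was -1.56 (adjusted p = 0.00025; adjusted p = 0.54 with an estimated correlation), and control 2 was the array richest in these markers. Sugar metabolism genes went both ways, 9 of 34 lower, including pklr (-4.20 ± 0.42) and the glucose transporter gene slc2a2 (-3.20 ± 0.42, or -0.73 with its mutant levels set at the 10th percentile of their arrays), and 3 higher. Their median was 0.16 while the list ranked lower without passing the test (adjusted p = 0.48). Of 25 liver transcription factors 5 were lower, foxa1 (-1.82 ± 0.29) and nr1h3 (-1.70 ± 0.26) among them, and 2 higher, one being rarga (1.81 ± 0.31; list adjusted p = 0.38). Adjusted over the list alone, 9 sugar genes were lower and 4 higher, and 6 transcription factors lower and 3 higher. The 72 ribosomal protein genes, 2 of them called higher and 1 lower, ranked lower with a median of -0.07 that became 0.11 after cyclic loess (adjusted p = 0.0091; adjusted p = 0.72 with an estimated correlation).

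Genes of matrix, skin and muscle rose in mutants. Of 31 collagen and fibrosis genes 19 rose, or 26 when adjusted over the list alone, and none fell. They included ccn2a (2.91 ± 0.52), dcn (2.22 ± 0.38) and tgfbi (1.79 ± 0.37), and the median was 1.64 (adjusted p = 8.5e-12; adjusted p = 0.19 with an estimated correlation). Of 17 epidermis markers 13 rose (15 when adjusted over the list alone), including cldne (2.85 ± 0.45), krt4 (2.47 ± 0.48) and anxa1a (1.73 ± 0.33). Of 28 skeletal muscle markers 15 rose, including myog, myod1 (1.86 ± 0.31) and pvalb3 (1.81 ± 0.31), while 1 fell, and adjusted over the list alone 24 were higher and 2 lower. Both lists ranked higher (adjusted p = 4.9e-08 and 1.5e-09; adjusted p = 0.19 and 0.2 with an estimated correlation). Of 21 leukocyte markers 3 rose, cxcr4b (2.38 ± 0.43), laptm5 (1.65 ± 0.40) and coro1a (1.49 ± 0.35, its other probe set -0.02). The myeloperoxidase gene mpx fell (-3.29 ± 0.55), although its other probe set gave 1.14. When adjusted over the list alone 8 leukocyte markers were higher and 1 lower, and the list ranked higher (adjusted p = 0.0023; adjusted p = 0.33 with an estimated correlation). Erythrocyte markers (2 of 12 called higher, including sptb at 1.06 ± 0.22) also ranked higher. So did p53 and damage genes (3 of 33 called higher, ccng1 at 1.29 ± 0.29, gadd45ba at 1.65 ± 0.41 and rps27l at 0.95 ± 0.18) and cilia and planar cell polarity genes (5 of 24, including wnt11 at 2.79 ± 0.56 and fzd7a at 1.73 ± 0.35). In these 3 lists 6, 3 and 6 were higher and 0, 0 and 1 lower when adjusted over the list alone. Their adjusted p values were 0.019, 0.0067 and 0.025, with adjusted p = 0.46, 0.19 and 0.19 with an estimated correlation. Of 12 hedgehog and glypican genes 4 rose, also when adjusted over the list alone, among them boc (2.22 ± 0.41), gli2a (1.62 ± 0.45) and gpc1b (1.70 ± 0.50). The list did not pass the test (adjusted p = 0.053), and gpc1b and gli2a lost their calls in 8 and 5 of the 11 fits without 1 array. Of 20 Notch genes 2 rose (5 when adjusted over the list alone), lfng (1.51 ± 0.30) and notch2 (1.11 ± 0.29, its other probe set -0.15; list adjusted p = 0.11). Of the 2 measured PDGF genes pdgfaa rose (1.55 ± 0.35), a call lost without mutant 4 or mutant 6.

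In the antigen presentation list, where azacytidine raised 6 genes, no member was called in mutants. The median of its 13 genes was 0.09, and -0.05 or -0.03 under the other scalings, with an unadjusted p under 0.05 in limma for 1 higher and 1 lower and 0 called when adjusted over the list alone. The interferon list held 1 called gene, gbp1, and the inflammation list 3 higher, including socs3a (2.67 ± 0.66), and 2 lower, the same counts as when adjusted over the list alone (list adjusted p = 0.38 for both). DNA methylation and chromatin genes were called higher for 2 of 30, both gadd45 genes. Of 17 germline genes sycp1 was higher (1.75 ± 0.34) and tdrd5 lower (-1.93 ± 0.51, or -1.18 with its mutant levels set at the 10th percentile), the latter call lost in 6 of the 11 fits without 1 array. These counts were the same when adjusted over the list alone, and neither list ranked apart (adjusted p = 0.15 and 0.76). No member of the neural, eye and lens, endocrine pancreas, endothelial or cell cycle lists was called, and 0, 0, 1, 1 and 4 had an unadjusted p under 0.05 in limma. The biliary list had 2 of 13 higher (adjusted over the list alone 6 higher and 2 lower; list adjusted p = 0.085), the intestinal list 1 of 15, and the heat shock list 2 of 25 higher. Oxidative stress genes had 3 higher and 5 lower of 33, fat synthesis genes 2 lower of 16, and cholesterol synthesis and proteasome lists 1 lower each. Adjusted over the list alone, 5 oxidative stress genes were higher and 6 lower, 3 fat synthesis and 1 cholesterol gene lower, 1 intestinal gene higher, and 0 heat shock or proteasome genes called. None of these lists ranked apart, and the medians of the cell cycle, fat synthesis and heat shock lists, 0.09, 0.05 and 0.00, were -0.03, -0.06 and -0.12 when arrays were centred.

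The mutant counts moved with single arrays and with scaling. Without mutant 6 there were 329 higher and 427 lower, without mutant 4 435 higher, and without controls 1 and 2 in turn 434 and 452 higher. With arrays centred on their medians 41% of calls were higher, against 51.5% as deposited, the median change over all probe sets moving from 0.08 to -0.03. With the marker covariate 13 probe sets were called higher and 102 lower. Among those were crp (-6.62), tdo2a (-5.28), ahsg1 (-4.71) and me1 (-4.45) lower and gbp1 (5.42) and myog (2.98) higher. The 8 falls named first all kept their calls with that covariate. Of the 8 rises named first, only gbp1 and myog did, and myog is itself in the muscle list. The rises of cfl1l, cxl34b.11, apodb, col10a1a, ch25hl1.1 and pycard lost theirs (limma adjusted p = 0.086 to 0.47). Among genes named for mutants, laptm5 and notch2 lost their calls in 4 of the 11 fits without 1 array, socs3a and gadd45ba in 3, and apodb in 2. The calls of ccng1 and coro1a were each lost in 1, without mutant 4 at 1.00 and without mutant 6 at 1.06.

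The comparison of both groups with shared controls asked how far drug and mutation moved the same genes. Of 12784 probe sets, 10 were called higher in both, against 3.2 for independent lists of those sizes. Simulations of unchanged groups against shared controls gave 0.01. They hold no true change to call, so that count was near 0 in advance and does not measure chance overlap. The 10 included lemd1, gbp1 and the NF-kB inhibitor gene nfkbiab. Also among them were the inhibin subunit gene inhbb (1.25 ± 0.23 with azacytidine and 1.57 ± 0.25 in mutants) and bmb (2.79 ± 0.26 and 1.46 ± 0.28). None was called lower in both, where independent lists would give 1.3. At an unadjusted p under 0.05 in limma 64 were lower in both, of 1270 lower with azacytidine and 1446 lower in mutants. No value for independent lists was computed for that count, so it does not show shared falls. A further 7 were called higher with azacytidine and lower in mutants. Among them were ahsg1, c4b, hpxb (2.04 ± 0.37 and -1.38 ± 0.40) and the citrate transporter gene slc13a5a (1.98 ± 0.27 and -1.22 ± 0.29). Another 4 did the reverse, among them pvalb3, tmem38a and actn3b. Independent lists would give 3 and 1.4, and division of the controls between the comparisons gave 1 to 36 and 0 to 381. Across all probe sets, which are not independent, the log2 changes correlated at -0.15, while unchanged groups sharing these controls gave 0.46. The covariance was -0.07 against 0.055 simulated, an excess of -0.125. The simulated noise was independent between probe sets and held no shared tissue content. The centred mean of muscle, epidermis and neural markers was -1.18 to -0.61 with azacytidine, -0.47 to 0.71 in controls and 0.87 to 1.44 in mutants. Opposite tissue content and opposite effects of drug and mutation therefore cannot be told apart by these values. When the controls were divided between the comparisons, the correlation ranged from -0.47 to -0.06 and the number higher in both from 3 to 12. The count called in the same direction was 6 without control 1, without azacytidine array 6 or without mutant 4, 20 without azacytidine array 1, and 0 with the marker covariate. Of the genes named here, nfkbiab lost its call in mutants in 10 of the 11 fits without 1 array, actn3b in 9, hpxb in 8, lemd1 in 4, slc13a5a in 2 and tmem38a in 1. With azacytidine inhbb lost it in 7 and hpxb in 5.

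Mutants set directly against azacytidine-treated livers tested whether the effects of mutation and drug differ. They differed in 3753 probe sets, 2329 higher and 1424 lower in mutants, and 3232 and 1934 at an unadjusted p under 0.05. Among named genes without overlap, the largest differences were lower crp (-6.70 ± 0.23), ahsg1 (-6.11 ± 0.33), igfbp1b (-5.50 ± 0.48), cyp4v2a (-5.48 ± 0.55, or -2.60 with its mutant levels set at the 10th percentile) and the chemokine gene ccl19a.1 (-5.44 ± 0.56). The largest on the higher side were col10a1a (5.18 ± 0.51), myog (5.14 ± 0.38), tcnbb (5.14 ± 1.11), fxyd11 (4.44 ± 0.61) and lye (4.37 ± 0.97). Mutant 3 was lowest of the mutants for lye (5.95 against 9.92 and 11.15) and tcnbb (9.38 against 12.4 and 11.89). Over the fits without 1 array lye ranged from 3.3 to 5.9 and tcnbb from 4.55 to 6.06, both highest without mutant 3. Antigen presentation genes were lower in mutants for 10 of 13 (b2m by -3.47 ± 0.53, cd74a by -4.64 ± 0.50), ER stress genes for 25 of 38 (dnajc3a -3.72 ± 0.35, hspa5 -2.5 ± 0.24) and proteasome genes for 13 of 38 (psma2a -1.22 ± 0.19). Hepatocyte markers were lower for 20 of 22, coagulation genes for 12 of 15 (f7i -4.16 ± 0.33) and cholesterol synthesis genes for 5 of 12 (hmgcs1 -2.84 ± 0.39, msmo1 -2.48 ± 0.54). These 6 counts were 10, 27, 15, 20, 12 and 7 when adjusted over the list alone, and 1 cholesterol synthesis gene was higher either way. Their adjusted p values were 3e-06, 2.4e-12, 1.6e-05, 3.8e-14, 1.3e-07 and 0.0044, and adjusted p = 0.23, 0.21, 0.21, 0.21, 0.21 and 0.23 with an estimated correlation. Epidermis (14 of 17 higher, cldne 4.12 ± 0.45, anxa1c 3.26 ± 0.40), skeletal muscle (25 of 28 higher, desma 3.08 ± 0.40), collagen (25 of 31 higher) and neural markers (14 of 21 higher) were higher in mutants, with 14, 25, 27 and 18 when adjusted over the list alone, while 1 muscle marker was lower either way and 1 collagen gene lower over the list alone (adjusted p = 7.4e-08, 4.9e-11, 4.4e-09 and 5.3e-05; adjusted p = 0.21, 0.21, 0.23 and 0.41 with an estimated correlation). The lists of complement, lipoproteins, fatty acid oxidation, bile acids, methionine cycle, xenobiotic metabolism, respiratory chain, amino acid catabolism and cell cycle genes also ranked lower in mutants, with 8, 10, 20, 6, 12, 10, 35, 18 and 5 members lower. In the same order 2, 0, 1, 2, 1, 1, 0, 1 and 0 members were higher, and adjusted over the list alone 8, 12, 21, 6, 13, 11, 39, 22 and 0 were lower and 2, 1, 1, 2, 1, 1, 1, 1 and 0 higher. Their adjusted p values ran from 4.9e-11 for the respiratory chain to 0.026 for bile acids, with adjusted p = 0.21 to 0.67 with an estimated correlation. The ahcy transcript differed by -0.64 ± 0.16 (adjusted p = 0.013), a call lost without mutant 4 or mutant 6 (-0.53 and -0.55). Scaling moved the direction of calls: 62.1% of calls were higher as deposited, 49.8% after cyclic loess and 44.1% after centring, the median over all probe sets moving from 0.14 to -0.02 and -0.08. Without mutant 6, 1408 were higher and 912 lower, and with the marker covariate 0 and 9 (unadjusted p under 0.05 for 369 and 710 in limma).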

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

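Levels within groups of 4 arrays were screened for 1 array far from the other 3, a screen that chance alone trips in about 1 of 20 groups; this screen was fixed before the data were examined. It picked out 11 of 314 groups, where 16 would be expected by chance. Azacytidine array 6 had an exocrine pancreas list mean of 6.97 against 5.33 to 5.58 in the rest of its group, a prss1 level of 9.16 against 7.14 to 7.19, and an fzd7a level of 4.98 against 5.51 to 5.6. Azacytidine array 1 had an inflammation list mean of 7.67 against 8.50 to 8.65, an anxa1c level of 6.54 against 7.81 to 7.88 and a gnmt level of 11.05 against 10.89 to 10.91. In azacytidine array 2 c7b was at 6.57 against 8.95 to 9.34. Control 1 had b2m at 6.20 against 5.09 to 5.22, myog at 5.16 against 6.29 to 6.51 and pvalb3 at 5.82 against 6.22 to 6.28. In control 4 tdrd5 was at 3.79 against 6.21 to 6.25.

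Among the 20 zebrafish array control probe sets, which no comparison used, 2 for skeletal muscle actin were higher on each mutant array than on any control array. Lower levels were not screened. The probe set at the 3' end averaged 12.59 in mutants against 10.63 to 12.01 in controls, and the middle one 10.41 against 6.71 to 9.23. A probe set at the 5' end of the same transcript went the other way, with a mean of 6.75 against 7.07 to 7.77, while another there overlapped between the groups (6.69 to 6.81 against 6.78 to 7.41).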

How the results depend on the processing

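Leaving out controls 2 and 4 together, the marker covariate and lists without shared members were chosen after seeing the data; other settings were fixed before. With the variance prior untrended or robust, the number as a random block (consensus correlation 0.029), a minimum change of 1 and dim probe sets left out, each count of calls stayed within 1.5 times, except that 35 were lower with azacytidine under the detection filter. Where a cause is not given below, the cause was not tested.

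For azacytidine, cyclic loess gave 92 higher and centring 97. Array weights gave 129 higher, 98 lower and 27 in the same direction in both comparisons. Fits of 2 groups, with fewer arrays, gave 497 higher in mutants against controls. Averaging probe sets, which tests fewer features, gave 1378 higher in mutants against azacytidine and 6 in the same direction. An unmoderated comparison, which borrows no variance across probe sets, gave 1 and 1 with azacytidine, 4 and 23 in mutants, 429 and 272 between them, and 0 in the same direction. Without controls 2 and 4 there were 19 higher with azacytidine, 347 higher and 430 lower in mutants, and 6 in the same direction. With the marker covariate there were 10 and 4, 13 and 102, and 0 and 9 (unadjusted p under 0.05 in limma for 369 and 710). It left 0 in the same direction and 12 lists with azacytidine. With an estimated correlation camera called 0, 0 and 0 lists (7, 6 and 6 at unadjusted p under 0.05). With azacytidine fry called 6, and in the other comparisons 20 and 25. Lists without shared members gave 20, 20 and 19.

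With the sample number as a replicate block, which leaves 2 residual degrees of freedom, calls were 0 and 0 with azacytidine (unadjusted 606 and 589 in limma), 0 and 9 in mutants (unadjusted 1009 and 823), 82 and 137 between them, and 0 in the same direction. Deviations of same-numbered arrays correlated at -0.21 to 0.03 (4 pairs), those of other pairs at -0.23 to 0.21. These values show no pairing by number, but 4 pairs are too few to exclude a shared clutch or day.

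Leaving out 1 array at a time gave 28 to 77 higher and 4 to 94 lower with azacytidine, 329 to 957 and 427 to 772 in mutants, and 1408 to 2500 and 912 to 1419 between them. It gave 6 to 20 in the same direction and 17 to 21, 17 to 22 and 18 to 21 lists. Of 145 gene results, 143 kept direction and side of the threshold with an untrended prior, 128 with 2 groups, 106 without controls 2 and 4, 21 with the block and 40 with the covariate. Values that turned sign were ahcy with azacytidine when centred (0.04), with the block (0.02) and without azacytidine array 5 (0.04, the other end of its range being -0.15 without array 6). The others were dnmt1 in mutants against azacytidine with the block (-0.18) and the covariate (-0.60), and gpc1b in mutants (-0.09) and syt1a with azacytidine (0.02), both with the covariate. List tests were not run with the random block, the minimum change or the unmoderated comparison, nor single genes with the last 2. Levels near background limit what dim probe sets can show.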

Other observations

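The tests of hepatocyte share, other cell types, RNA quality, leukocytes and time of day were chosen after the results were seen; the regroupings of arrays were planned. The RNA quality test first used GAPDH alone, by which RNA quality was excluded; the actin condition was added after that result was seen. The leukocyte test first left out 3 markers held by other lists, by which leukocytes as a whole were argued against; as the called cd74a and cd74b were among them, all 21 markers are used. The list of clock genes was written after per2 and nfil3-5 had been seen. It placed genes in an activating arm and in an arm activated by the clock's core factors. Whether each gene, such as nfil3-5, nfil3-6 or cry5, follows its arm was not tested. Of the 10 other genes it placed in the activated arm, 8 were lower with azacytidine, with a median of -0.69. Among them were ciarta (-1.18 ± 0.24, adjusted p = 0.053) and nr1d2b (-1.09 ± 0.30, adjusted p = 0.12). None of these 10 passed the test. In mutants their median was 0.27, and nfil3-6 fell by 1.92 ± 0.44 (adjusted p = 0.016). The difference between the treatments was not tested for this list.

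Livers collected at another time of day may have lowered per2 and nfil3-5. In that case the activating arm should have moved the other way, and its 4 genes had a median of 0.04. That value goes against the prediction, while the other genes placed in the activated arm moved as it says (median -0.69). The prediction holds only if each gene follows its arm, and a shift between hours at which the activating arm stands at 1 level was not examined. Time of day and an effect of the drug on the clock cannot be told apart here, and the labels used here give no hour of collection.

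Lower hepatocyte markers in mutants could come from a smaller share of hepatocytes in the dissected tissue. A smaller share lowers all members by 1 amount only if no other cells make them and the scale compresses none of the changes. Of the 22 members 16 lay over 2 standard errors from the list median. Among the 8 with control levels away from the compressed top and the floor, 5 lay that far from their own median (changes of -5.12 to -0.6). These spreads argue against share as the whole cause only under those conditions, which were not tested. Replacement by all other cell types alike would move their marker lists alike, and 5 of 55 pairs moved apart by over 3 standard errors. The pairs reuse the same lists and no number expected by chance was computed, so this does not decide it. Lower RNA quality cannot be told apart from an effect of the mutation: controls 4 and 8, with GAPDH 3' to middle differences (4.15 and 4.36) above the lowest in a mutant (3.22), had a hepatocyte mean 0.18 above that of controls 1 and 2, but no control reached the actin 3' to 5' difference of the mutants (5.59 to 6.21, against at most 4.92). The actin measures do not settle it, since the 3' to middle difference went the other way (1.8 to 2.89 against 2.76 to 3.92) and the 3' level rose with the muscle markers (12.59 against 11.45), and particular tissues carried along, such as skin and muscle, stay open beside the mutation.

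Higher antigen presentation genes with azacytidine may reflect more leukocytes. The 21 leukocyte markers, cd74a and cd74b included, had a median of 0.41 and an upper quartile of 1.47, against a median of 2.05 for antigen presentation genes. More leukocytes and an effect of the drug on liver cells themselves cannot be told apart here, since most markers rose far less than the antigen presentation genes but 7 were higher when adjusted over the list alone. Among markers in no other list, ctss2.1, grna.1, marco and grna, all picked for a rise of over 1, were at 3.27 ± 0.71, 1.75 ± 0.61, 1.64 ± 0.55 and 1.47 ± 0.33 (adjusted p = 0.068, 0.2, 0.18 and 0.07).

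For the count of probe sets called, only the real split among 35 gave as many in each comparison. The counts were 74 with azacytidine (highest among other splits 16), 1547 in mutants against controls (highest 139) and 3753 in mutants against azacytidine (highest 747). These margins argue against chance division of the arrays. They do not exclude it, because 1 of 35 is the lowest share that these splits can give. For the 20 lists with azacytidine the real split stood highest (highest other 18; 1 of 35), a margin too narrow to exclude chance. Nor was it excluded for the 20 lists in mutants against controls (highest other 21; 5 of 35) or the 19 in mutants against azacytidine (highest other 22; 7 of 35). The other splits gave a median of 12, 13.5 and 15 lists, so the preset correlation calls many lists in arbitrary groupings too, and the real count with azacytidine was 17 without control 4. For probe sets called the same way in both comparisons the real value was 10, and 2 of 100 regroupings gave as many. This excludes nothing, because only 1 of the 99 other regroupings had calls in both comparisons, which fixes the shared count at 0 in the rest. All 10 were higher, against 3.2 for independent lists, a value that leaves out the shared controls. With the controls divided the count was 3 to 12, which still holds both treatment effects and is no chance value. Chance overlap therefore stays open. The highest other regrouping, 1048, points to a structure of the samples: it had all 3 mutants and control 4 in the control role, while the 2 others with all mutants there, beside control 1 or azacytidine array 2, gave 0. Control 4 lay nearest the mutants on the first principal component (26.5, against 56.9 to 91.6).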
